A study of Homo sapiens with 2 samples.

How the data were processed

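Total RNA was taken with ISOGEN from 22Rv1 cells that were untreated or treated with 25 µM luteolin, both at 48 h. Per the labels, 250 ng of it was marked with the dye Cy5 and hybridized to a Toray 3D-Gene miRNA array in a single colour. There was 1 array per condition. Each array held 3200 spots: 2565 miRNA probes spotted once, 320 blank spots, and control probes and other spots. Because a probe was spotted once and a condition had 1 array, the number of arrays limits the precision, and no p-value between conditions was computed.

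The deposited files give scanner intensity on a linear scale, in steps made by the authors. Per the file headers these are raw data, background subtraction and global normalization, and for the luteolin array a further adjusted column. Their construction was worked out from the values. The authors subtracted a constant per array, equal to the mean of the blank spots after trimming 5% at each end, and listed a value only where the raw signal exceeded that mean by more than 2 SD. This rule gave the authors' listing for all 2565 miRNAs on both arrays. They then multiplied each array by a factor, 3.03 for the control array and 5.77 for the luteolin array, that puts the median of the listed miRNAs at 25. The adjusted column multiplies the luteolin array by a further 0.803. That number equals the median, over the 701 miRNAs listed on both arrays, of the control over luteolin ratio, so the median log2 ratio on this scale is 0 by construction. The basis of this step is not given in the sources used here. The deposited summary table of intensity holds the globally normalized control values and the adjusted luteolin values. These are called the authors' scale.

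The setting fixed before the data were examined, called the offset scale, took the raw signal of all spots, corrected it with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, quantile-normalized the 2565 miRNA probes of both arrays, and took log2. With most signals only a few units above the blanks, adding this offset to both arrays pulls ratios towards 0, so the authors' scale, one of the alternatives fixed beforehand, is printed beside it. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A miRNA counted as detected above the trimmed blank mean plus 2 SD, which was 84.0 units on the control array and 67.3 on the luteolin array. Differences are luteolin over control, counted over miRNAs detected on both arrays at an absolute log2 ratio of 1 or more. A miRNA above the Negative Control spots on the luteolin array alone was given a bound, its luteolin level over the highest Negative Control spot of the control array on the authors' scale, a floor chosen after the data were seen. That spot, at 93.7 units, belonged to Negative Control 1. The highest spots of Negative Control 2 and Negative Control 3 on that array were 82.9 and 84.9 units. The bound assumes the authors' scaling between the arrays and makes no allowance for the error of the luteolin spot.

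The standard error of a log2 ratio combines the SD of the blank spots with the spread between repeated spots of 5 bright control probes, whose pooled coefficient of variation was 7.34% on the control array and 6.23% on the luteolin array. It describes error between spots within an array only, and can be too small for dim miRNAs. The blank SD, taken after the trimming, was 1.48 units on the control array and 0.591 on the luteolin array. Repeated spots of Negative Control 1 had SDs of 2.68 and 0.778, and those of Negative Control 2 had 1.38 and 0.497.

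The lists of miRNAs, 21 in number, were fixed before the data were examined from general knowledge of families, clusters, androgen and p53 biology, luteolin, markers of other cell types and troublesome catalogue entries. A list was summarised by its median log2 ratio over members detected on both arrays, with at least 3 required, and by the percentile of that median among 10000 random lists of the same size matched in 10 bins of mean intensity. The percentile describes this pair of arrays and is not a test of the treatment. The rule for named miRNAs, also fixed beforehand, took the 12 largest differences in each direction that met the size rule in the brighter part of the detected miRNAs, up to 5 per direction detected on 1 array with a bound of at least 2-fold, the 10 brightest of each array, up to 4 members of each list, and miR-8080. It gave 75 miRNAs. Names added afterwards are marked in the text.

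The procedure was tested on simulated arrays with 2565 miRNAs, of which 200 were altered and 881 came out as detected on both. The offset scale found 12 of 48 miRNAs raised 4-fold, 2 of 37 lowered 4-fold, and 0 of 45 raised and 0 of 46 lowered 2-fold. Blank subtraction with median scaling found 48, 35, 22 and 23 of these. It called 44 of 705 unchanged miRNAs and the offset scale called 0. Of 100 unaltered lists, 0 fell outside the central 95% of random lists on the offset scale and 2 with blank subtraction. The random lists could include altered miRNAs and the unaltered lists could not, which favours low counts. The simulated arrays had a single gain and independent spot noise, so these counts do not give the rate on the real arrays.

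The alternatives fixed beforehand were an offset of 16, no background correction, blank subtraction with median scaling, scaling to the 75th percentile, no normalization between arrays, quantile normalization over detected miRNAs, cyclic loess, the authors' scale, no detection filter, the brighter part of the miRNAs alone, thresholds of 1.5-fold and 3-fold, a detection limit at 3 SD, unmatched random lists and list means. Scaling to the Spike Control spots and a limit at the highest Negative Control spot were added after the data were seen. The median log2 ratio of the 701 miRNAs was -0.02 on the offset scale, -0.26 with blank subtraction and median scaling, -0.13 without normalization, 0.81 with spike-in scaling and 0 on the authors' scale. Genome positions are not printed because the files name no genome build. Probe sequences were not used.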

Results

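MicroRNA levels were measured in 22Rv1 cells, an established human prostate cancer cell line that expresses the androgen receptor. One culture was left untreated and the other received 25 µM luteolin, a flavone found in many plants, and both were taken at 48 h. Each condition was measured on 1 array, so there was no replicate and no test between the conditions could be run. The differences below describe this pair of arrays, and their errors, written as ±, are standard errors from the spread between repeated spots within an array. These errors cover neither culture nor array variation and can be too small for dim miRNAs. Of 2565 miRNA probes, 811 (31.6%) gave a signal above the detection limit on the control array and 984 (38.4%) on the luteolin array, and 701 did so on both. Where a pair of log2 ratios or list medians is given, the offset scale comes first and the authors' scale second, and a single ratio of a miRNA is on the authors' scale unless stated. Most signals lay close to background. The median blank-subtracted signal of the detected miRNAs was 8.24 units on the control array, where the blank spots averaged 81.0 units with an SD of 1.48. On the luteolin array that median was 4.33 units, against a blank mean of 66.2 and an SD of 0.591. The detection limit thus lay closer to the blanks on the luteolin array, so the detected counts do not compare how many miRNAs were present.

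The comparison asks which miRNAs differ in level after luteolin. The miRNA with the largest log2 ratio on the offset scale was miR-21-5p (MIMAT0000076), a widely studied oncogenic miRNA that the androgen receptor is reported to induce, at 1.15 ± 0.09. On the authors' scale its level was 157 on the control array and 867 on the luteolin array, a 5.52-fold difference with a log2 ratio of 2.46 ± 0.14, the largest there among the 310 miRNAs that exceeded every Negative Control spot on both arrays. Over all 701 the first place on the authors' scale went to hsa-miR-582-5p, named after its value was seen, whose control signal lay inside the range of those spots. Measured against the highest of them it was at least 1.64-fold higher. This bound, like those below, assumes the authors' scaling between the arrays and makes no allowance for spot error. MiR-141-3p, an epithelial miRNA of the miR-200 family, stood second on the offset scale at 0.93 ± 0.09, and at 1.96 ± 0.14 on the authors' scale, where it went from 180 to 701. The collagen-repressing miR-29b-3p stood at 0.78 ± 0.07 and 2.01 ± 0.16, and miR-148a-3p, another miRNA reported to respond to androgen, at 0.70 ± 0.06 and 2.29 ± 0.19. The direction of miR-21-5p, miR-141-3p, miR-29b-3p and miR-148a-3p was the same under every scaling tried.

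By the rule set for size, an absolute log2 ratio of 1 or more, 1 miRNA (miR-21-5p) was higher on the luteolin array and 0 were lower on the offset scale. On the authors' scale 94 were higher and 36 lower, 130 in all, but this split depended on the scaling: 52 were higher and 75 lower with blank subtraction and median scaling, and 281 higher and 0 lower with spike-in scaling. The scales differ in background method, offset and normalization at once. With the offset of 50 kept, the other normalizations gave 1 to 3 miRNAs, so normalization alone did not make the gap. Blank subtraction without an offset gave 127 with median scaling, 130 on the authors' scale and 281 with spike-in scaling. The shares of background method and offset were not separated, and an offset of 16 in place of 50 gave 4 miRNAs. In simulated arrays the offset scale found 25.0% of 48 miRNAs raised 4-fold and called 0 of 705 unchanged ones, while plain blank subtraction with median scaling found all 48 and called 6.2% of the unchanged ones. Both scales are therefore given side by side. Among the 310 miRNAs above the Negative Control spots, a limit chosen after the data were seen, 57 were at least 2-fold higher on the authors' scale and 2 lower; hsa-miR-149-5p, at -1.32 ± 0.26, and hsa-miR-8078, at -1.27 ± 0.32, were those 2, named after their values were seen.

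**Figure D1:**
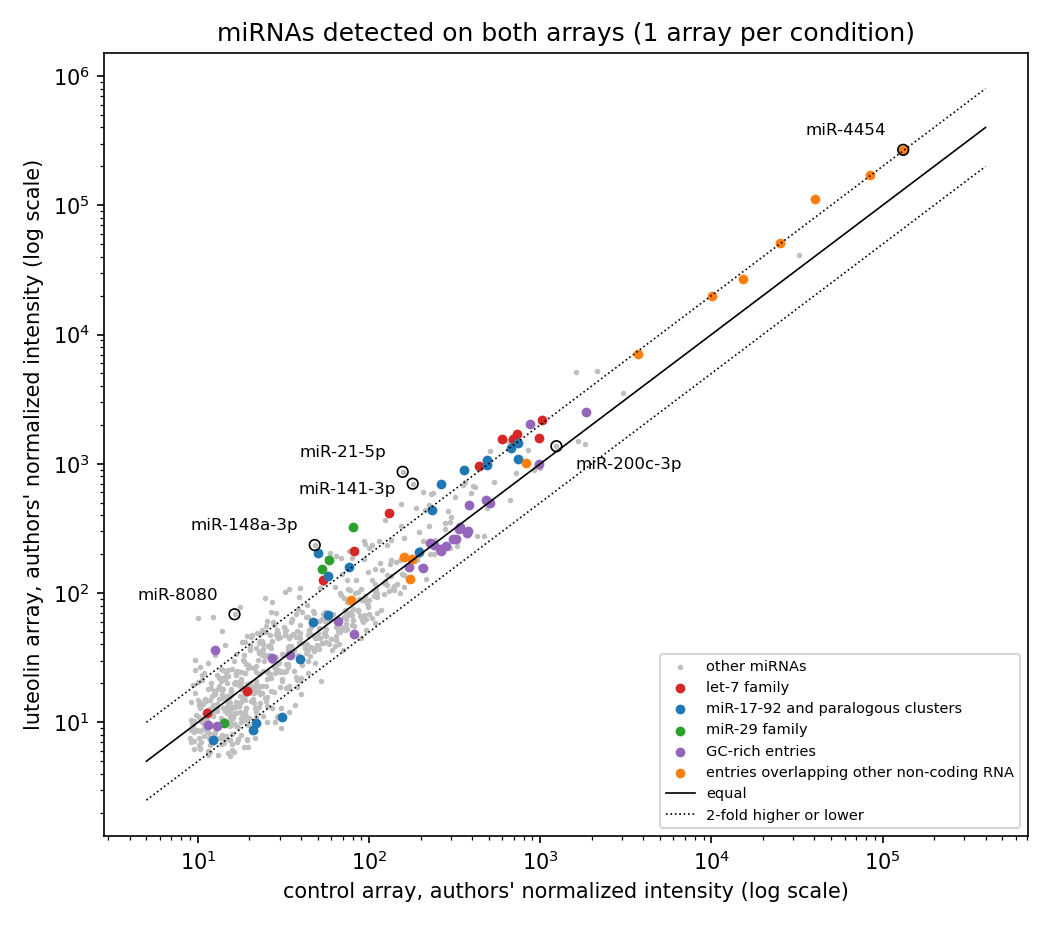
Authors' normalized intensity of each miRNA detected on both arrays, control array on the horizontal axis and luteolin array on the vertical axis, both on log scales, with 1 array per condition. Each point is 1 miRNA, colours mark 5 of the preset lists, the solid line marks equal levels and the dotted lines a 2-fold difference; miR-21-5p (157 and 867) lies above the upper dotted line and most let-7 members lie near or above it.

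The let-7 family, tumour-suppressive miRNAs linked to differentiation, was higher on the luteolin array as a group. Of its 11 members detected on both arrays, 10 had a ratio above 0 on the offset scale, with a list median of 0.41, at percentile 99.8 of 10000 random lists matched on intensity. On the authors' scale the median was 1.16 (percentile 99.6), and 8 members were at least 2-fold higher and 0 at least 2-fold lower. The number at least 2-fold higher was 0 on the offset scale, 3 with blank subtraction and median scaling, and 9 with spike-in scaling. The members with the largest ratios were let-7g-5p at 0.65 ± 0.08 on the offset scale and 1.67 ± 0.15 on the authors' scale, let-7f-5p at 0.60 ± 0.12 and 1.38 ± 0.14, and let-7d-5p at 0.60 ± 0.12 and 1.22 ± 0.14. The brightest of the named members, let-7a-5p, stood at 1028 on the control array and 2190 on the luteolin array.

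The miR-29 family, whose members repress collagens, had a median of 0.40 over 4 detected members (percentile 99.7) and of 1.58 on the authors' scale (percentile 99.9), where 3 members were at least 2-fold higher. These were miR-29b-3p, miR-29c-3p at 1.64 ± 0.18 and miR-29a-3p at 1.53 ± 0.19. The fourth, miR-29b-2-5p, lay below the highest Negative Control spot on both arrays. With undetected members included the list stood at percentile 95.6, inside the central 95% of random lists. The miR-17-92 cluster and its paralogs, which MYC and E2F factors induce in proliferating cells, had a median of 0.21 over 19 members (percentile 99.9), or 0.92 on the authors' scale (percentile 99.6). Here 7 members were at least 2-fold higher on the authors' scale, among them miR-19a-3p at 2.02 ± 0.19, miR-19b-3p at 1.41 ± 0.14 and miR-106b-5p at 1.31 ± 0.14, and 3 were listed as at least 2-fold lower. These 3 did not exceed the Negative Control spots on both arrays, so the size of their differences is not defined. The split was 3 higher and 3 lower with blank subtraction and median scaling, and 13 and 0 with spike-in scaling. With undetected members included, the median was -0.01 over 28 members (percentile 54.1), with 15 of them below 0.

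Detected miRNAs of the androgen-responsive list also stood high. Their median was 0.27 over 8 members (percentile 99.7) and 0.81 on the authors' scale (percentile 98.8). On the latter 4 members were at least 2-fold higher: miR-21-5p, miR-148a-3p, miR-141-3p and miR-27a-3p, the last at 1.27 ± 0.14. There 5 members were above 0 and 3 below, with 0 at least 2-fold lower. With blank subtraction and median scaling 4 were at least 2-fold higher and 1 lower. With no normalization the offset-scale median was 0.13 (percentile 99.2), with 4 members above and 4 below 0. Among the brighter miRNAs alone it was 0.60 over 6 members. MiRNAs reported to act on androgen receptor transcripts, with miR-8080 left out, had a median of 0.31 over 5 members (percentile 98.0) and of 1.16 (percentile 97.8), with let-7c-5p at 1.16 ± 0.14 and miR-30b-5p at 1.19 ± 0.15 on the authors' scale. MiRNAs reported to respond to luteolin in other cells had a median of 0.32 over 4 members (percentile 99.98) and of 2.15 on the authors' scale (above all 10000 random lists), but of these only miR-21-5p exceeded every Negative Control spot on both arrays. On the control array miR-34a-5p and miR-301a-3p lay below the highest such spot, and measured against it they were at least 1.70-fold and 2.35-fold higher; miR-21-3p lay below it on both arrays. These 3 lists overlap with others: 4 of 8, 4 of 5 and 3 of 4 of their detected members belong to another list as well. None of the 3 stayed outside the central 95% of random lists with undetected members included, where the percentiles were 74.9, 20.1 and 80.4. The androgen receptor-targeting list was also inside it with 75th percentile scaling and with no normalization (97.45 in both), with cyclic loess (97.09), with the list mean (96.1) and above the Negative Control spots (94.6). The androgen-responsive and luteolin-responsive lists were used without the reported direction of each response. A high median therefore shows neither the reported response nor its reverse.

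GC-rich entries of the miRNA catalogue, which often give strong array signals, were lower than other miRNAs of like intensity. Their median was -0.27 over 26 members on the offset scale (percentile 0.010), with 24 of 26 below 0, and -0.10 on the authors' scale (percentile 0.975). Examples were miR-6087 at -0.53 ± 0.09 and -0.36 ± 0.14, and miR-6125 at -0.52 ± 0.09 and -0.32 ± 0.14, both of which turned positive under spike-in scaling, as did the list median (0.71). MiR-6089 stood on the other side at 0.61 ± 0.12 and 1.22 ± 0.14. On the authors' scale 8 of 26 members were above 0, with 2 at least 2-fold higher and 0 at least 2-fold lower. Across the 17 lists with at least 3 detected members, 6 lay above and 1 below the central 95% of random lists on the offset scale. For lists of unrelated miRNAs 0.85 would be expected outside it. Members of a family share sequence and several lists share members, so that number is no chance level for these lists. With members above the Negative Control spots on both arrays only, 13 lists had at least 3 members, and let-7, miR-17-92, androgen-responsive and miR-29 lay above the range and GC-rich entries below it.

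**Figure D2:**
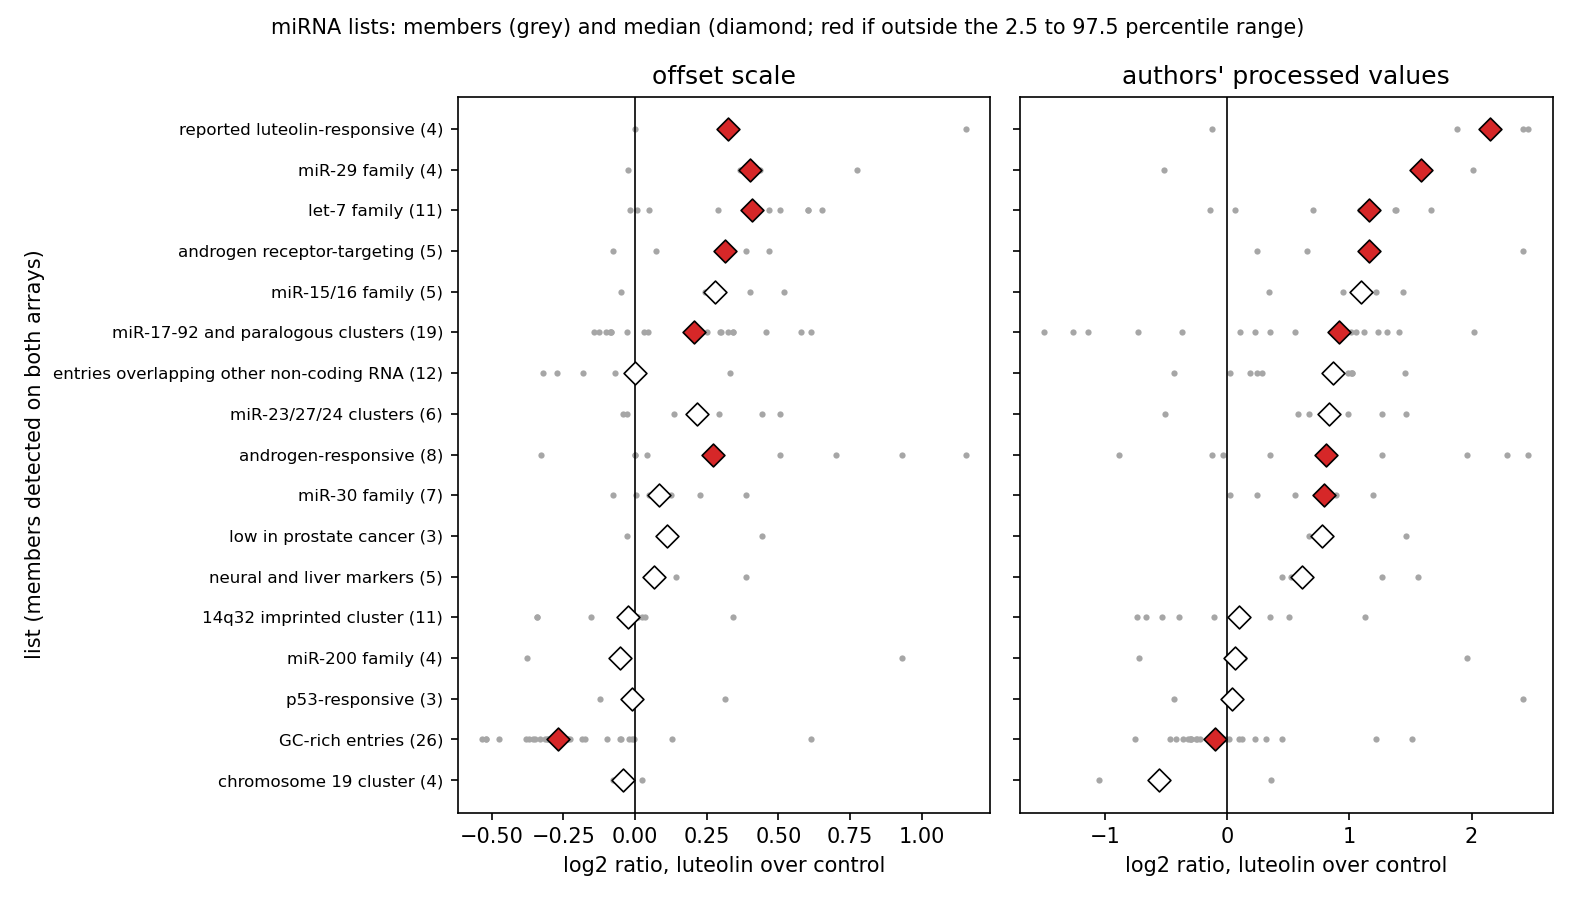
Log2 ratio, luteolin over control, of the members of each list (grey points) and the list median (diamond), on the offset scale at left and on the authors' scale at right, with members detected on both arrays counted in brackets. Red diamonds lie outside the central 95% of intensity-matched random lists; the let-7 median is 0.41 at left and 1.16 at right, and the GC-rich median, which turned positive under spike-in scaling, is -0.27 and -0.10.

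The other lists lay inside that range on the offset scale. The miR-15/16 family, which represses cyclins and BCL2, had a median of 0.28 (percentile 92.5) and of 1.10 on the authors' scale (percentile 93.7), with miR-15a-5p at 1.44 ± 0.17 and miR-16-5p at 1.22 ± 0.14. The miR-23/27/24 clusters had medians of 0.22 (percentile 92.5) and 0.83 (percentile 86.5). The miR-30 family had a median of 0.08 (percentile 96.6), which was below 0 without normalization between the arrays, and of 0.79 on the authors' scale, where it passed the range at percentile 97.8. Members of the miR-200 family, which hold down ZEB1 and ZEB2 in epithelial cells, moved apart: miR-141-3p was 3.90-fold higher, miR-200b-3p stood at 0.00 ± 0.16 and miR-200c-3p at 0.14 ± 0.14 on the authors' scale, although the last was -0.38 ± 0.12 on the offset scale. The family's medians were -0.05 and 0.07. The p53-responsive list had medians of -0.01 (percentile 58.9) and 0.04 (percentile 51.1), set by miR-194-5p, which lay below the highest Negative Control spot on the control array. Of its 3 detected members, miR-34a-5p was at least 1.70-fold higher and miR-192-5p stood at -0.44 ± 0.19. MiRNAs reported as low in prostate cancer had medians of 0.11 (percentile 81.1) and 0.77 (percentile 77.7) over 3 of 21 members, which are the values of miR-221-3p alone; below the highest Negative Control spot on the control array, it was at least 1.55-fold higher against it. Of the cluster of miR-183, miR-96 and miR-182, often high in prostate carcinoma, miR-182-5p (1.27 ± 0.22 on the authors' scale) and miR-96-5p were the arms detected on both arrays, and miR-96-5p, below the highest Negative Control spot on the control array, was at least 2.21-fold higher against it.

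MiRNAs of other cell types and silent loci were mostly at or below the limit of detection, as were most probes: 701 of 2565 were detected on both arrays. The neural and liver markers, at 5 of 15, were not below that share, while the other lists in this paragraph were. The imprinted 14q32 cluster had 11 of 89 arms detected on both arrays, with medians of -0.02 (percentile 39.1) and 0.10 (percentile 71.0). Its median was also positive with 75th percentile scaling, cyclic loess and spike-in scaling, and below 0 in the other scalings. Among the brighter miRNAs alone it was -0.15 over 5 members (percentile 14.3). The chromosome 19 cluster had 4 of 46, with medians of -0.04 (percentile 7.23) and -0.55 (percentile 18.2). Of these 4, 0 exceeded the Negative Control spots on both arrays, and the median turned positive under 75th percentile and spike-in scaling (0.26 in the latter). The Xq27 testis cluster had 1 of 30, miR-513a-5p at -0.75 ± 0.21. Blood and endothelial markers had 2 of 15, miR-451a at -0.85 ± 0.28 and miR-486-3p, which lay below the highest Negative Control spot on both arrays, and muscle and stromal markers 0 of 14. Neural and liver markers had 5 of 15, with medians of 0.07 (percentile 90.0) and 0.62 (percentile 88.6), led by miR-9-5p at 1.56 ± 0.19, and the offset-scale median turned to -0.07 with no normalization. The 0.62 was the value of miR-128-3p, named after its value was seen. Like miR-9-3p, it lay below the highest Negative Control spot on the control array.

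The brightest signals came from entries whose sequences overlap tRNA, rRNA or other structured RNA. On both arrays miR-4454 was the brightest, at 132106 and 268562 on the authors' scale, followed by miR-7975 and miR-7977. The 5 brightest miRNAs took 75.4% of the blank-subtracted signal of detected miRNAs on the control array and 80.3% on the luteolin array. The log2 ratio on the authors' scale was 1.02 ± 0.14 for miR-4454, 1.01 ± 0.14 for miR-7975, 1.45 ± 0.14 for miR-7977, 1.02 ± 0.14 for miR-5100 and 0.35 ± 0.14 for miR-4284. On the offset scale quantile normalization set several of them to 0.00 because they held the same rank on both arrays, and there miR-4284 stood at -0.33 ± 0.14. The list of 12 overlapping entries had medians of 0.00 (percentile 64.4) and 0.87 (percentile 85.7). Of the bright miRNAs with changed rank, miR-4723-5p stood at 0.82 ± 0.13 and 1.68 ± 0.14, and miR-6822-5p at -0.61 ± 0.13 and 0.20 ± 0.14, so that its direction depended on the scale.

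The level of miR-8080 (MIMAT0031007) was compared because this miRNA was known from the study of luteolin in this cell line. It was named in the design for that reason before the data were examined. The choice was not independent of earlier work on this treatment. For miR-8080 a high ratio here is therefore no independent evidence. Its raw signal on the luteolin array, 81.0 units, lay above the 16 Negative Control 1 spots there, 66.8 to 69.4, while on the control array its raw signal of 86.4 lay inside their range, 83.2 to 93.7. Set against the highest Negative Control spot of the control array, miR-8080 was at least 1.77-fold higher on the luteolin array on the authors' scale. This bound assumes the authors' scaling between the arrays and makes no allowance for spot error. The listed values were 16.4 and 68.5 on that scale, a log2 ratio of 2.07 ± 0.42, and the offset scale gave 0.30 ± 0.05. The highest control-array spots of Negative Control 2 and Negative Control 3 were 82.9 and 84.9 units, below miR-8080. Since its control signal was not resolved from the Negative Control 1 spots, the size of these ratios is not defined beyond the bound, and 1 pair of arrays does not show whether the level differs after treatment.

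**Figure D3:**
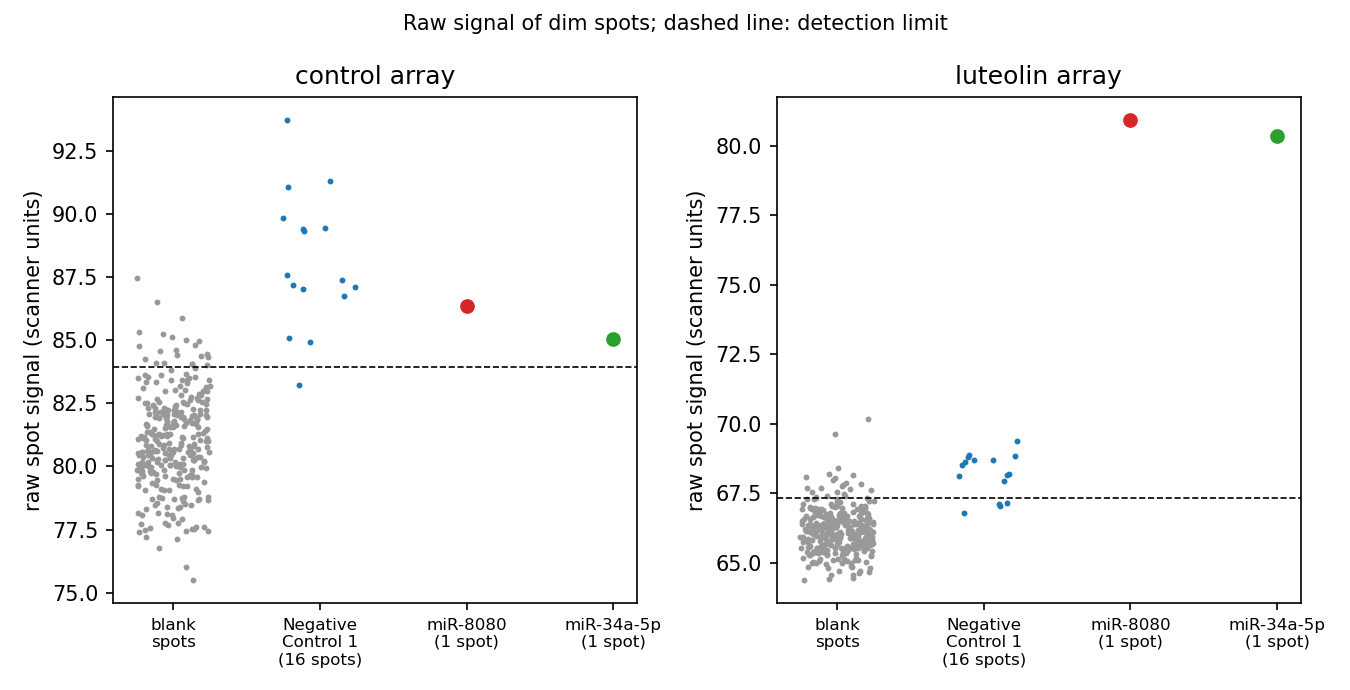
Raw signal in scanner units of the blank spots, the 16 Negative Control 1 spots, miR-8080 and miR-34a-5p on the control array at left and on the luteolin array at right, with the detection limit as a dashed line (84.0 and 67.3). On the control array miR-8080, at 86.4, lies among the Negative Control 1 spots, and on the luteolin array, at 81.0, it lies above them.

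A further 110 miRNAs were detected on the control array alone and 283 on the luteolin array alone. The floors differed: the highest Negative Control spot was 93.7 units on the control array, over a blank mean of 81.0. On the luteolin array it was 69.4, over 66.2. The larger counts on the luteolin array in this paragraph therefore do not show that more miRNAs were present after luteolin. Of the former, 0 exceeded the highest Negative Control spot of the control array, so none is named. Of the latter, 50 exceeded that of the luteolin array. Measured against the highest Negative Control spot of the control array on the authors' scale, 1 of these 50 had a bound above 1-fold, and 0 reached 2-fold. This was miR-590-5p at 1.09-fold, named after its value was seen. The bounds make no allowance for spot error, so one this close to 1 does not show a higher level. Against the laxer detection limit of the other array, 67 of the 110 and 30 of the 283 had a nominal bound of at least 2-fold on the authors' scale and 0 of either on the offset scale; for the 67 this compares signals not resolved from the Negative Control spots and gives no usable fold. Among miRNAs detected on both arrays, 232 exceeded the Negative Control spots on the luteolin array alone. Against the highest Negative Control spot of the control array, 55 of them had a bound above 1-fold, some of these close to 1. A bound of at least 2-fold was found for 5, led by miR-7-5p at 2.79-fold and miR-4291 at 2.65-fold, also named afterwards. All bounds assume the authors' scaling, on which the median log2 ratio of the 701 miRNAs is 0. That median was -0.61 for blank-subtracted signal without scaling and -0.26 with median scaling, where the bounds are lower. With spike-in scaling it was 0.81, where they are higher. Bounds of at least 2-fold were not counted on those scales.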

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

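Except for the lists themselves and the settings fixed beforehand, all tests in this part were chosen after the result was seen. The tests of the intensity trend, of the single factor for miR-8080 and of spot noise each replaced an earlier version: percentiles of the lists with cyclic loess, first over a set with the miR-15/16 family (94.32) and then over the lists below (99.38 or more, and 97.09 for the androgen receptor-targeting list), a ratio in spot standard errors, and a count of dim miRNAs.

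Signal was found at spots that the comparisons do not use. Of the 85 spots marked as having no probe, 9 on the control array and 8 on the luteolin array exceeded the detection limit, 6 of them on both. Set on the authors' scale, spot 43 of these gave 522 on the luteolin array and 286 on the control array, spot 51 gave 147 and 102, spot 78 gave 339 and 191, and spot 80 gave 125 and 87.6. Among the 22 single-spot probes named S-Probe1001 to S-Probe1022, S-Probe1006 gave 29.9 on the luteolin array and 17.4 on the control array, S-Probe1008 gave 260 and 169, and S-Probe1018 gave 311 and 253. Of these 22, 14 exceeded the limit on the control array and 15 on the luteolin array, and not all were higher on the latter: S-Probe1009 gave 23.4 on the luteolin array and 42.1 on the control array, while the brightest, S-Probe1014, gave 3075 and 2900. What these spots carry is not given in the sources used here.

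The let-7, miR-17-92, androgen-responsive, miR-29, luteolin-responsive and androgen receptor-targeting lists lay high on the luteolin array over their detected members. For the first 4 lists the shift exceeded the trend of the ratio with intensity among all detected miRNAs. Cyclic loess narrowed the medians of 10 intensity bins, taken from the median of all, from between -0.15 and 0.21 to between -0.02 and 0.03. Each of the 4 kept at least 85.2% of its shift (let-7 the least). Each stood at least 4.16 SDs of random lists above the highest bin. The lists were picked for lying beyond random lists matched on intensity, so this outcome largely followed from the choice and is no independent evidence. For the other lists the trend is neither supported nor excluded: the luteolin-responsive list kept 110% of its shift but only 1 of its members exceeded every Negative Control spot on both arrays, and the androgen receptor-targeting list kept 102% but stood 2.41 such SDs above, under the 3 set as the limit. A GC-dependent difference in hybridization between the arrays is a candidate explanation that stays open: the GC-rich list kept a median of -0.25 with cyclic loess, below all 10000 random lists, although probe sequences were not used and the GC content of the other lists was not measured. An effect of luteolin stays open as well, untested with 1 array per condition.

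The higher level of miR-8080 on the luteolin array was weighed next. A single signal factor for the whole array, set at the median ratio of all detected miRNAs, predicts 22.6 units on the control array, 3.67 SDs of the Negative Control 1 spots above the highest Negative Control spot (12.8), while miR-8080 lay below that spot. Against noise between spots the same prediction gives 6.43 such SDs to the measured signal, or 3.52 without any scaling. The earlier count found 4 of 391 dim miRNAs, miR-8080 included, with a ratio as high and 0 with one as low. These dim miRNAs did not exceed the highest Negative Control spot on the control array, while their luteolin signal had no such cap. That filter favours high over low ratios, so the count says nothing about noise. Neither the single factor nor noise is excluded, since the distances in SDs set 1 dim spot per array against the spread of another probe within an array. The control signal, 86.4 units raw, was not resolved from the Negative Control 1 spots (83.2 to 93.7), so the ratio may be smaller or larger than listed. A fault of a single spot and an effect of luteolin were not tested.

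The Spike Control spots were lower on the luteolin array, with a mean log2 ratio of -1.42 and an SD of 0.07 over 16 spots. Spike Control 1 stood at 9223 blank-subtracted units on the control array and 3503 on the luteolin array, and Spike Control 2 at 9148 and 3352. S-Probe26, S-Probe27 and S-Probe28, with 8 spots each, were lower as well, at -1.28, -1.27 and -1.32. A single factor for the whole array is argued against as the cause, since the 10 brightest miRNAs had a median of 0.39 (from -0.41 to 0.84) on the same scale. Whether the amount of these control targets or of miRNA differed was not tested, and no biological explanation was tested.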

How the results depend on the processing

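The settings with spike-in scaling and with the Negative Control limit were chosen after the data were seen; the others were planned. No paired analysis was possible because each condition had 1 array. On the offset scale 1 miRNA differed by at least 2-fold; the count was 4 with an offset of 16, 127 with blank subtraction and median scaling (52 higher, 75 lower), 3 with 75th percentile scaling, 2 with cyclic loess, 281 with spike-in scaling (all higher), 130 on the authors' scale (94 higher, 36 lower), 59 on that scale above the Negative Control spots, 21 at 1.5-fold and 0 at 3-fold. It stayed at 1 with no background correction, no normalization, quantile normalization over detected miRNAs, no detection filter and the brighter miRNAs alone. Above the highest Negative Control spot 310 miRNAs were detected on the control array and 592 on the luteolin array, where that spot lay closer to the blanks. The number of lists outside the percentile range was 7, and 4 without a detection filter (let-7 and miR-15/16 above, GC-rich and chromosome 19 below), with 5 to 10 in the other settings. The log2 ratio of miR-8080, 0.30, was 0.64 with an offset of 16, 0.23 with no background correction, 1.81 with blank subtraction and median scaling, 0.15 with no normalization, 2.88 with spike-in scaling and 2.07 on the authors' scale, and positive in every setting run. Of 666 alternative values of 74 named miRNAs, 271 stayed within 1 spot standard error, 395 moved further and 53 had the opposite sign, 23 of them under spike-in scaling. Of 232 list values, 152 stayed within their spread and 80 moved further. An offset pulls ratios towards 0 and a scaling factor moves them all by construction; what else shifted the values was not tested. Low signal over background limits the dim miRNAs.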

Other observations

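The tests of hairpin arms and of neighbouring genes were set out before their results were seen; the repeats on miRNAs above the Negative Control spots, and the 95% bound that the arm correlation had to clear, were added afterwards.

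Among neighbours in the genome, miR-141-3p stood at 1.96 on the authors' scale and miR-200c-3p, from the same primary transcript, at 0.14. In the same way let-7c-5p stood at 1.16 and miR-99a-5p, named after its value was seen, at -0.15, and miR-30b-5p at 1.19 and miR-30d-5p at 0.25. Other neighbours lay close together, such as miR-195-5p at 0.95 and miR-497-5p at 1.10.

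A change in the hairpin precursor, or base composition that both arms share, would make the 5p and 3p arms differ alike. Across 94 hairpins with both arms detected, the ratios had Pearson r = -0.058 (two-sided permutation p = 0.579) and Spearman rho = -0.049 (p = 0.642), and r = -0.073 without the 2 hairpins farthest from the median. The arms shared a sign in 45 of 94. Hairpins are not independent replicates, and the upper 95% bound of r, 0.147, exceeds the 0.1 set as the limit. Spot noise in dim arms also pulls r towards 0, so neither a weak nor a strong relation is excluded. With both arms above the Negative Control spots, 14 hairpins remained (r = 0.03, permutation p = 0.923; rho = 0.16, p = 0.574; r = 0.15 without the 2 farthest).

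Co-transcription of neighbouring hairpins would bring the ratios of hairpins within 10 kb together. Each hairpin was given the mean ratio of its detected arms, dim arms included, so these values differ from those of the single arms above. Over 58 pairs of hairpins the median absolute difference was 0.601, against 0.629 in pairs redrawn at matched intensity (permutation p = 0.391), which decides nothing either way. Gene positions were found for 549 of 606 hairpins. With the arms above the Negative Control spots alone, 30 pairs remained and the median was 0.578.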
